A study of Mus musculus with 12 samples.

How the data were processed

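RNA was measured in 12 murine neuroblastoma tumors, 3 untreated controls and 3 tumors each labelled 24, 48 and 72 h for high intensity focused ultrasound (HIFU). Per the labels, tumors were grown by inoculating neuroblastoma cells into A/J mice, and the frozen tissue was ground under liquid nitrogen. The RNA was hybridized to Affymetrix Mouse Clariom S arrays, 1 array per tumor. The titles place the tumors at a number of hours and the treatment label says for that number, so reading the times as hours after HIFU is an assumption. Whether the 3 tumors of a group came from separate animals is not stated in the labels, so p-values measure the spread between these samples, which may in part be technical.

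The values deposited by the authors were log2 signals per probe set, from 1.75 to 19.93, for 22206 probe sets. The log scale and its base were read from the range of the values and are not given in the sources used here; every fold below rests on base 2. Transcriptome Analysis Console 4.0 is named in the submitters' processing notes. The summarization, the background correction, the filters and the genome build are not given in the sources used here, so no coordinates are printed. The median signal lay between 5.43 and 5.68 on the 12 arrays, and no further scaling was applied. Normalization between arrays of this kind removes most of a shift common to all genes, so each change below is mainly relative to the other genes on the array. The medians still differed, from 5.43 to 5.45 in controls and from 5.52 to 5.68 at 72 h. Arrays give no read depth, and their number, 3 per group, limits the precision.

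Probe sets were named through the platform's annotation, with symbols looked up by gene number in a RefSeq table of assembly GRCm38.p6. One symbol was found for 19572 probe sets, several for 0 and none for 2634, and all 19572 were in the RefSeq table. There were 55 symbols on more than 1 probe set. Probe sets without a symbol were tested and counted but not named, and genes of the lists without a named probe set here, among them Foxp3, were not analysed here.

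Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 3.37), with a mean per group fitted to all 12 arrays. The contrasts were each time against control, each pair of times, the mean of the 3 HIFU groups against control, and a moderated F test over the 3 contrasts with control. All tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over all 22206 probe sets, with a threshold of 0.05. Errors beside log2 differences are limma standard errors (SE); errors beside group signals are standard deviations (SD, n = 3). Python 3.11.15 was used for the figures.

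Gene lists for 45 cell types, pathways and processes were fixed before the data were examined. Each was tested against all other genes with camera, with its preset inter-gene correlation of 0.01 and 1 probe set per gene, the one with the highest mean. Adjusted p-values of lists are Benjamini-Hochberg values over the 45 lists and the 3 times. Camera with a correlation estimated per list and fry, which tests whether the genes of a list move on balance one way, were run beside it. A list that passed the preset test is said to have risen or fallen. Counts of members whose 3 HIFU arrays lay on one side of all 3 controls are given beside the 5% that chance gives in 1 direction. That 5% holds for a single gene. Members of a list move together and share the same arrays, so such a count is not a test.

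The genes named in the text follow a rule fixed before the data were examined. For each time against control, it takes the 6 largest rises and 6 largest falls among probe sets past the threshold whose 3 arrays lay on one side of the controls, with predicted genes left out. Where fewer passed, it adds the next by unadjusted p. It also takes up to 4 members of each described list by the p of the F test, 18 measured genes of interest for tumor immunity and stress, and 3 rises and 3 falls per pair of times. Genes outside the rule are named as such.

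The fit was tested on simulated data with 200 changed genes among 22206, for 24 h against control. It found 16% of those changed by 1 log2 unit, 70% at 2, 92% at 4 and 100% at 6, with 3 false calls among 142. In that simulation a shifted list was found and 0 of 44 other lists were called. The simulated genes varied independently of one another. The simulation therefore does not show how often lists are called falsely where genes move together.

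Alternatives chosen before the data were examined were a block for the replicate number, leaving out the 25% of probe sets with the lowest mean, quantile normalization, median centring, an intensity trend with robust estimation, array weights, only the groups compared, an unadjusted p with a 2-fold change, only probe sets with a symbol, the mean of a gene's probe sets, and leaving out each array in turn. A pseudocount was not tried, because the values were already on a log scale. Chosen after seeing the data were a covariate for skeletal muscle (per array, the median over the skeletal muscle list of each gene's difference from its mean over the 12 arrays), and a fit without the 4 arrays high in marrow genes, HIFU_48h replicate 3 and the 3 HIFU_72h arrays. The closing section gives their effect.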

Results

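Gene expression was profiled in 12 neuroblastoma tumors, a tumor type of the sympathetic nervous lineage, grown in A/J mice, an inbred strain. The 3 control tumors were untreated. Of the others, 3 tumors each were labelled 24, 48 and 72 h for HIFU, in which focused sound waves break up tissue. The series names mechanical fractionation as the mode. The times were read as hours between HIFU and sampling, which the wording of the labels does not settle. The comparisons ask which genes differed from untreated tumors at each time, and which differed between times. Values are log2 signals per probe set, and differences are log2 differences.

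Arrays of the same group correlated with r between 0.951 and 0.993 across probe sets (median 0.973), and arrays of different groups between 0.915 and 0.988 (median 0.973). By the median, arrays of a group were no more alike than arrays of different groups. The first principal component held 43.6% of the variance, and HIFU_72h replicate 2 lay farthest out on it, at 126 against -78.9 for control replicate 2 at the other end. The tumors differed in their content of skeletal muscle transcripts. The median of the 18 skeletal muscle genes lay 1.41 and 0.54 below the control mean in control replicates 1 and 2 (-1.41 and -0.54) and 2.18 above it in control replicate 3. In the 9 HIFU arrays it lay between 2.02 above, in HIFU_24h replicate 2, and 5.68 above, in HIFU_72h replicate 2.

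At 24 h, transcripts of the acute-phase protein lipocalin 2, of muscle protein breakdown and of metallothioneins were higher than in untreated tumors. Lcn2 (probe set TC0200003303.mm.2), whose product binds bacterial siderophores and is stored in neutrophil granules, rose 176-fold, from 7.02 ± 0.92 (SD, n = 3) to 14.49 ± 0.99, a log2 difference of 7.46 ± 0.74 SE (limma, adjusted p = 0.00589). Trim63 and Fbxo32, which encode the muscle ubiquitin ligases MuRF1 and atrogin-1, rose by 7.43 ± 0.93 SE (adjusted p = 0.0227) and 5.65 ± 0.72 SE (adjusted p = 0.0247). Pdk4, a kinase that restrains pyruvate oxidation, rose 107-fold, by 6.74 ± 0.66 SE (adjusted p = 0.00589). Myf6, a transcription factor of muscle fibers, and Hspb7, a small heat shock protein of heart and muscle, rose by 6.35 ± 0.91 SE and 5.91 ± 0.83 SE (adjusted p = 0.039 for both).

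The metallothioneins Mt1 and Mt2, metal-binding proteins induced by stress and glucocorticoids, rose by 4.56 ± 0.57 SE (adjusted p = 0.0227) and 5.45 ± 0.79 SE (adjusted p = 0.039). Retreg1, a receptor for autophagy of the endoplasmic reticulum, rose by 5.64 (adjusted p = 0.00751), Cnksr1 by 4.59 (adjusted p = 0.0274) from a control signal among the lowest 25%. Abra, an actin-binding protein of muscle, rose by 3.67 (adjusted p = 0.039). These last 3 genes were named after their values were seen. The 1 probe set that fell was that of Cd72, a B-cell coreceptor, from 12.72 ± 1.68 to 7.38 ± 0.58, a difference of -5.33 ± 0.76 SE (adjusted p = 0.039). The next downward by unadjusted p did not pass. They were -4.30 for Aldoc, a glycolytic aldolase (adjusted p = 0.0956), -2.68 for Psmb8, an immunoproteasome subunit (adjusted p = 0.0931), and -2.02 for H2-K1, a class I heavy chain (adjusted p = 0.0956). Psme2, a proteasome activator, differed by -1.60 (adjusted p = 0.0956) and Itgax, the integrin CD11c, by -1.52 (adjusted p = 0.0853), to a signal among the lowest 25%. The muscle list moved with these rises, with a median of 3.37 above control at 24 h.

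Genes of interferon signaling and antigen presentation fell together at 24 h. The interferon-gamma-induced list had a median difference of -3.08 over 18 measured members (camera adjusted p = 4.13e-20; adjusted p = 0.473 with an estimated correlation). Over all genes 0 of its members passed, and 15 were lower when adjusted over the list alone. For 16 members all 3 HIFU_24h arrays lay below all 3 controls, against 5% by chance for a single gene. The members move together on the same arrays, so that excess is not a test. Among the members were the interferon-induced GTPases Igtp (-4.16 ± 0.76 SE), Iigp1 (-4.16 ± 0.80 SE) and Irgm1 (-3.50 ± 0.65 SE). The MHC class I list, which shares Psmb8, Psmb9 and Tap1 with the former, fell with a median of -1.81 (camera adjusted p = 3.49e-19; adjusted p = 0.362 with an estimated correlation). All 15 of its measured members were lower, 0 passed over all genes and 15 when adjusted over the list alone, and 15 had non-overlapping arrays. Fry also called this list at 24 h (adjusted p = 0.0294). H2-D1, the other classical heavy chain of the list, differed by -2.11 ± 0.42 SE. The 23 interferon-stimulated genes, led by Bst2 (-4.19 ± 0.78 SE), Xaf1 (-3.84 ± 0.79 SE), Usp18 (-3.17 ± 0.74 SE) and Mx2 (-2.15 ± 0.53 SE), fell with a median of -1.72 (adjusted p = 0.473 with an estimated correlation). Of these, 0 passed over all genes, 16 when adjusted over the list alone, and 15 had non-overlapping arrays.

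Proliferation genes also fell at 24 h. All 22 members of the cell cycle and mitosis list were lower, with a median of -0.72, and 4 passed when adjusted over the list alone. Among them were the mitotic kinesin Kif11 (-1.21 ± 0.27 SE) and the kinase Aurkb (-1.27 ± 0.32 SE). The DNA replication, histone and ribosomal protein lists fell with medians of -0.71, -0.56 and -0.53, with 0 members past the threshold adjusted over the list alone in each. The hypoxia list fell with a median of -0.65, with 6 of 23 members lower and 1 higher adjusted over the list alone; Stc2, a secreted glycoprotein, differed by -3.04 ± 0.56 SE and Ddit4, an inhibitor of mTOR signaling, by -1.95 ± 0.45 SE. MHC class II genes fell with a median of -0.98 (1 of 12 adjusted over the list alone; H2-Aa -2.66 ± 0.61 SE) and cytotoxic lymphocyte and NK cell genes with -0.44 (3 of 18; Klrk1 -1.62 ± 0.50 SE). Over all genes 0 members of these 7 lists passed, and each of the 7 had an adjusted p of 0.473 with an estimated correlation.

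Lists of other tissues and cell types rose at 24 h. The skeletal muscle list led with a median of 3.37, with 18 of 18 members higher, 0 past the threshold over all genes and 15 adjusted over the list alone; Acta1, skeletal actin, differed by 2.24 ± 0.56 SE and Tnni2, fast troponin I, by 4.58 ± 1.28 SE. Fibroblast genes rose with a median of 1.58, neutrophil genes with 1.15, alternatively activated macrophage genes with 1.08 and extracellular matrix genes with 1.07. Dcn, the matrix proteoglycan decorin, differed by 3.55 ± 1.32 SE, and Cd163, the hemoglobin scavenger receptor of macrophages, by 4.36 ± 0.99 SE. Smaller medians were those of endothelial cells (0.78), adipocytes (0.69), chemokines (0.62), coagulation (0.55), immediate-early genes (0.49), pericytes (0.37), heat shock (0.34), B cells (0.34), mast cells (0.26) and the haem and iron response (0.26). The latter held Mt1 and Mt2, its only members past the threshold over all genes, and Lcn2 was the only such neutrophil gene; the other 13 lists held 0. Adjusted over the list alone, 2 alternatively activated macrophage, 2 adipocyte, 2 heat shock and 3 haem and iron genes were higher and 1 lower, 2 chemokine genes were higher and 4 lower, and 0 or 1 in the others. With an estimated correlation the adjusted p of these 15 lists lay between 0.473 and 0.729. In the array with the highest muscle median at 24 h, HIFU_24h replicate 1 (5.36), the fibroblast median was 2.98, against 0.21 in HIFU_24h replicate 2, which had the lowest (2.02).

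**Figure D1:**
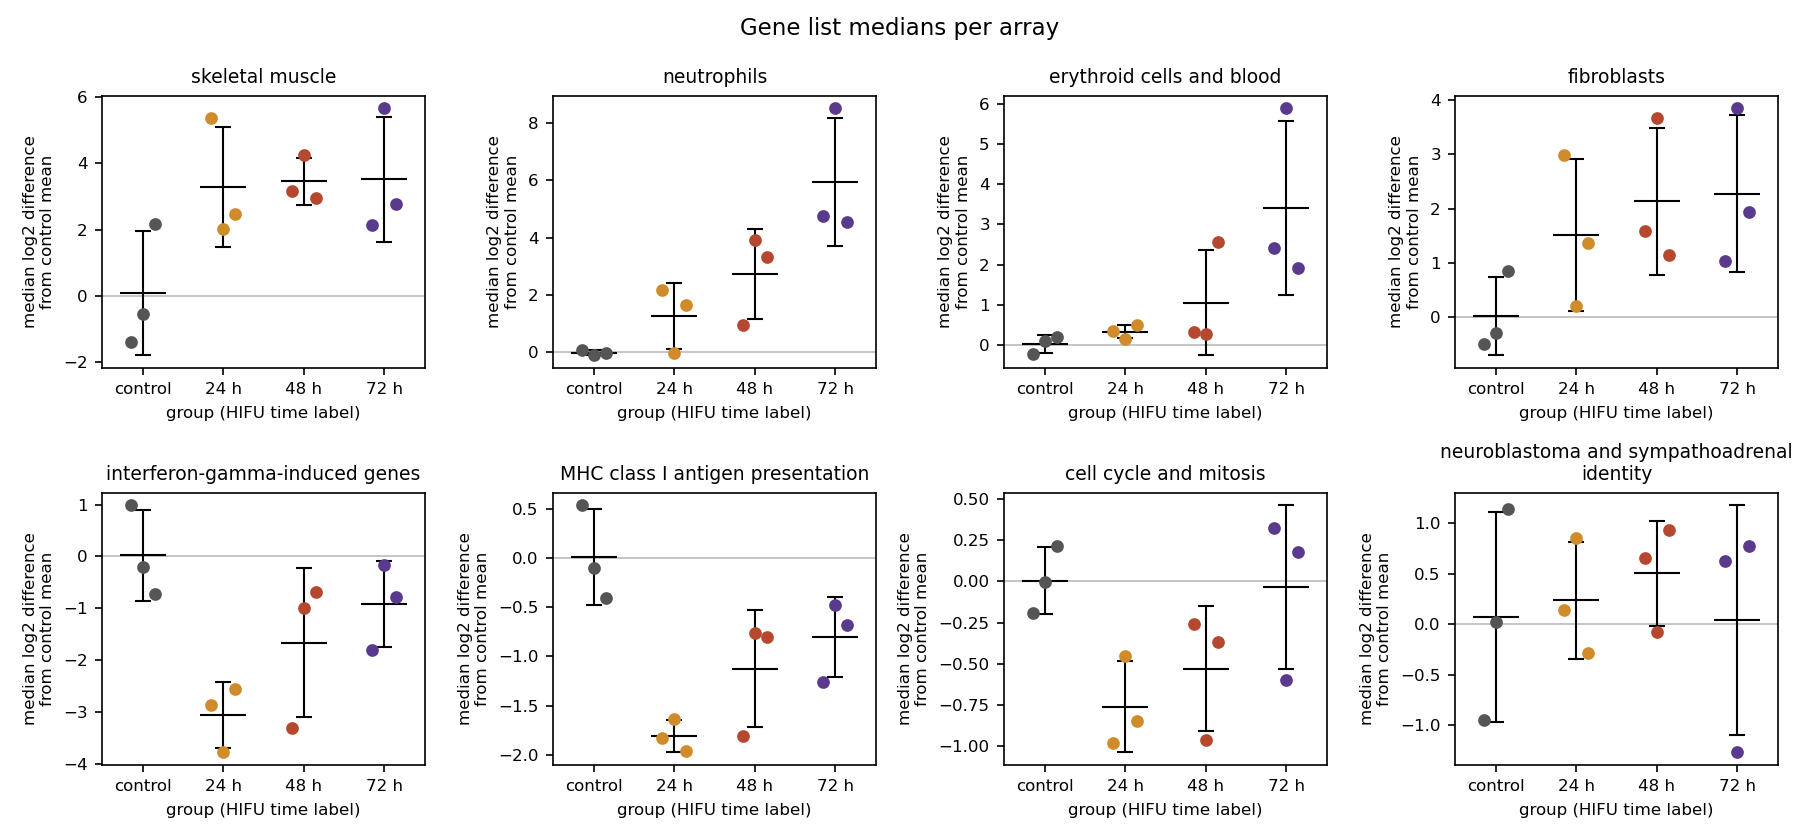
Median log2 difference from the control mean (y axis) of 8 gene lists in each array (dots), by group (x axis); long bars are group means and whiskers the SD of 3 arrays. The interferon-gamma and MHC class I medians of the 3 arrays at 24 h (-2.55 to -3.77 and -1.64 to -1.96) lay below all controls, and the neutrophil medians were highest at 72 h, between 4.53 and 8.53.

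At 24 h, 11 probe sets rose and 1 fell of 22206 (limma), and 2185 had an unadjusted p under 0.05, where 1110 would be expected by chance. The count depended on single arrays. It was 0 without control replicate 1, control replicate 2, HIFU_24h replicate 1 or HIFU_24h replicate 3. It was 253 (52 higher, 201 lower) without control replicate 3, 31 without HIFU_24h replicate 2, 23 without HIFU_72h replicate 2, 6 without HIFU_48h replicate 3, and 3 without HIFU_48h replicate 1 or HIFU_72h replicate 3. It was 8 without HIFU_48h replicate 2, 1118 (532 higher, 586 lower) with array weights, 3 with a block for the replicate number and 0 with a muscle covariate. With that covariate Lcn2 differed by 5.87 ± 0.75 SE, Pdk4 by 6.23 ± 0.89 SE, Trim63 by 5.47 ± 0.94 SE and Cd72 by -5.17 ± 1.05 SE. The differences were smaller, some errors were larger and fewer residual degrees of freedom were left. An adjusted p also depends on the p-values of the other probe sets. Which of these ended the gene calls was not tested. With the covariate, 8 of the 25 list calls were kept, 7 ended and 9 medians reversed (the muscle list was left out of that fit). Among the reversed were fibroblast genes, which passed as lower (-0.635, camera adjusted p = 0.0127), and neutrophil genes, which did not pass (-0.118, camera adjusted p = 0.802). Cell cycle genes kept their call with a smaller median (-0.258). Without HIFU_24h replicate 1 the calls of B cell (0.33), mast cell (0.25), pericyte (0.22), chemokine (0.44), heat shock (0.24), matrix (0.64) and haem and iron genes (0.085) ended. So did those of cytotoxic lymphocyte (-0.43), MHC class II (-0.59) and heat shock genes (0.039) without HIFU_24h replicate 2. The same held for B cell (0.29), mast cell (0.19), chemokine (0.38) and immediate-early genes (0.30) without HIFU_24h replicate 3. It also held for B cell (0.45), mast cell (0.31), pericyte (0.40) and chemokine genes (0.51) without control replicate 3. Single calls also ended for pericyte genes without control replicate 1 (0.31), for pericyte (0.36) and chemokine genes (0.65) without control replicate 2, and for chemokine genes without HIFU_48h replicate 1 (0.62). Quantile normalization ended those of B cell (0.27), mast cell (0.17) and pericyte genes (0.32), the block that of pericyte genes (0.37), and leaving out the lowest 25% of probe sets that of mast cell genes (0.44). Other medians moved by more than 1.5 times and stayed called. They were cytotoxic lymphocyte (-0.17) and heat shock genes (0.20) without control replicate 1, haem and iron genes (0.098) without control replicate 2, and endothelial (0.45) and fibroblast genes (0.88) without HIFU_24h replicate 1. Without HIFU_24h replicate 2 they were neutrophil (1.99), mast cell (0.48), pericyte (0.57), chemokine (0.96) and matrix genes (1.66), and without HIFU_24h replicate 3 alternatively activated macrophage (0.58) and heat shock genes (0.66).

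At 48 h, Lcn2 was the 1 probe set past the threshold, rising 272-fold to 15.11 ± 0.75 (SD, n = 3), a difference of 8.09 ± 0.74 SE (limma, adjusted p = 0.00512). The next by unadjusted p did not pass. They were 4.43 for Fbxo32, 4.41 for Pdk4, 4.19 for the muscle fatty acid binding protein Fabp3 and 3.86 for Retreg1 (adjusted p = 0.199 for each), and 4.02 for Mt1 (adjusted p = 0.188). Downward, by the same order, Cd72 differed by -4.46, Kctd17 by -1.88, Tor3a by -1.55, the lipid phosphatase Mtmr2 by -1.53, Ttyh2 by -1.50 and Itgax by -1.37 (adjusted p = 0.199 for each).

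The interferon and antigen presentation lists fell at 48 h as well, with medians of -1.85 for interferon-stimulated, -1.76 for interferon-gamma-induced, -1.19 for MHC class I and -0.78 for MHC class II genes. Adjusted over the list alone, 12 of 23, 7 of 18, 8 of 15 and 0 of 12 members were lower, with 0 over all genes. Bst2 differed by -3.20 ± 0.78 SE, Igtp by -1.80 ± 0.76 SE and H2-K1 by -0.94 ± 0.34 SE. The interferon-gamma medians of the 3 arrays were -3.31, -0.99 and -0.69, against -0.73 in control replicate 3, and the list median was -0.94 without HIFU_48h replicate 1 and -1.07 without control replicate 1. The cell cycle (-0.55), histone (-0.54), ribosomal protein (-0.49), hypoxia (-0.46) and DNA replication lists (-0.22) also fell, with 4, 3, 0, 5 and 0 members lower adjusted over the list alone. For these 9 lists the adjusted p with an estimated correlation was between 0.473 and 0.729, and 0 of their members passed over all genes.

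Skeletal muscle (median 3.31), neutrophil (2.32), fibroblast (2.15) and extracellular matrix genes (1.56) rose most at 48 h. All 19 neutrophil genes were higher, 1 passed over all genes and 5 adjusted over the list alone, and 12 had non-overlapping arrays; S100a9, a calcium-binding alarmin of granulocytes, differed by 5.96 ± 1.38 SE. The neutrophil medians of the 3 arrays were 0.94, 3.91 and 3.32, and the erythroid median was 2.57 in HIFU_48h replicate 3 against 0.34 and 0.28 in the other arrays. Of muscle genes 13 of 18 were higher adjusted over the list alone, and of fibroblast and matrix genes 0, with 1 matrix gene lower. Erythroid (1.01), adipocyte (1.00), alternatively activated macrophage (0.74), endothelial (0.73), keratinocyte (0.70), phagocytosis (0.63), chemokine (0.61), pericyte (0.56), coagulation (0.55), haem and iron (0.53) and mast cell genes (0.35) rose too. Adjusted over the list alone, 3 alternatively activated macrophage, 4 haem and iron, 2 keratinocyte and 2 pericyte genes were higher and 0 in the other 7 of these lists. Outside Lcn2, 0 members of the 15 lists passed over all genes, and the adjusted p with an estimated correlation was between 0.473 and 0.729.

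The count at 48 h was 1 of 22206 probe sets (limma), with 2956 at an unadjusted p under 0.05, where 1110 would be expected by chance. It was 0 with a block for the replicate number, and also without control replicate 1, control replicate 2, HIFU_48h replicate 2 or HIFU_48h replicate 3. It was 312 (52 higher, 260 lower) without control replicate 3, 10 without HIFU_72h replicate 2, 2 without HIFU_72h replicate 1. It was 6 with only the 2 groups compared, 944 (312 higher, 632 lower) with array weights and 0 with a muscle covariate (Lcn2 6.48 ± 0.75 SE). Under that covariate 8 of the 24 list calls were kept, 7 ended and 8 reversed (the muscle list was left out of that fit). Phagocytosis genes then passed as lower (-0.764, camera adjusted p = 0.00674). Neutrophil genes kept their call with a smaller median (0.664). The count was 2 without the 4 arrays high in marrow genes, a fit that ended the calls of keratinocyte (0.26), erythroid (0.37) and hypoxia genes (-0.24). List calls ended without HIFU_48h replicate 2 for DNA replication (-0.040), chemokine (0.23), matrix (0.90), mast cell (0.24), pericyte (0.23) and phagocytosis genes (0.35). Without HIFU_48h replicate 3 they ended for erythroid (0.37), hypoxia (-0.24) and keratinocyte genes (0.26). They also ended without control replicate 3 for DNA replication (-0.22), chemokine (0.28), erythroid (0.97), hypoxia (-0.24), mast cell (0.36) and pericyte genes (0.63). Further calls ended without control replicate 1 for MHC class II (-0.58) and erythroid genes (0.93), without control replicate 2 for chemokine genes (0.49), without HIFU_48h replicate 1 for MHC class II genes (-0.40). The last were those without HIFU_24h replicate 3 for DNA replication (-0.22) and erythroid genes (1.01), and without HIFU_24h replicate 1 or 2 for erythroid genes (1.01). Quantile normalization ended those of hypoxia (-0.39), mast cell (0.23) and DNA replication genes (-0.077), median centring that of DNA replication genes (-0.28), and leaving out the lowest 25% of probe sets those of MHC class II (-0.60), mast cell (0.41) and DNA replication genes (-0.22). Medians that moved by more than 1.5 times and stayed called were also those of DNA replication without control replicate 1 (-0.41) or HIFU_48h replicate 3 (-0.45) and alternatively activated macrophages without HIFU_48h replicate 1 (1.17). Without HIFU_48h replicate 2 they were those of endothelial (0.39), fibroblast (1.40), cell cycle (-0.31) and ribosomal protein genes (-0.27).

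At 72 h, 2 probe sets passed the threshold. Lcn2 rose 1360-fold to 17.44 ± 1.43 (SD, n = 3), a difference of 10.41 ± 0.74 SE (limma, adjusted p = 0.000348). Ibsp (bone sialoprotein) rose by 4.93 ± 0.59 SE (adjusted p = 0.0375), from a control signal of 2.72 ± 0.12 among the lowest 25% to 7.65 ± 1.23. The alarmin S100a8 differed by 11.08 ± 1.65 SE (adjusted p = 0.102), S100a9 by 9.83 ± 1.38 SE (adjusted p = 0.0876), the granule protein lactoferrin, Ltf, by 7.24 ± 0.97 SE (adjusted p = 0.0789) and Mrgpra2b by 4.96 ± 0.72 SE (adjusted p = 0.102), none past the threshold. S100a8 and Ltf also started from control signals among the lowest 25%, so the sizes of these differences are uncertain too. Downward, the first by unadjusted p were not past the threshold either. Aldoc differed by -3.64, Ddit4 by -2.58, the interferon-induced gene Ifi27 by -1.88, the circadian repressor Ciart by -1.88, the Notch target Hey2 by -1.48 and Mtmr2 by -1.45 (adjusted p between 0.146 and 0.255).

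The neutrophil list rose with a median of 5.58 at 72 h (camera adjusted p = 2.47e-26; adjusted p = 0.362 with an estimated correlation), and fry called it too (adjusted p = 0.0294). All 19 measured members were higher, 1 passed over all genes and 15 adjusted over the list alone, and 17 had non-overlapping arrays. Chance gives 5% for a single gene, but the members move together, so that excess is not a test. Ngp, a granule protein made by granulocyte precursors, differed by 12.78 ± 1.94 SE, from a control signal among the lowest 25% (3.07), as did Rhag (3.41) and Mmp8 (3.55) among the genes named for 72 h, so the sizes of these differences are uncertain. All 6 measured erythroid genes were higher, with a median of 3.41, 0 over all genes and 6 adjusted over the list alone; Rhag, a red cell membrane protein, differed by 5.55 ± 1.22 SE and Slc4a1, the anion exchanger of red cells, by 4.40 ± 1.07 SE (adjusted p = 0.473 with an estimated correlation). Per array, the neutrophil median was 4.76, 8.53 and 4.53 and the erythroid median 2.42, 5.89 and 1.92, with the highest of each in HIFU_72h replicate 2, which also had the highest muscle (5.68) and fibroblast medians (3.85).

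**Figure D2:**
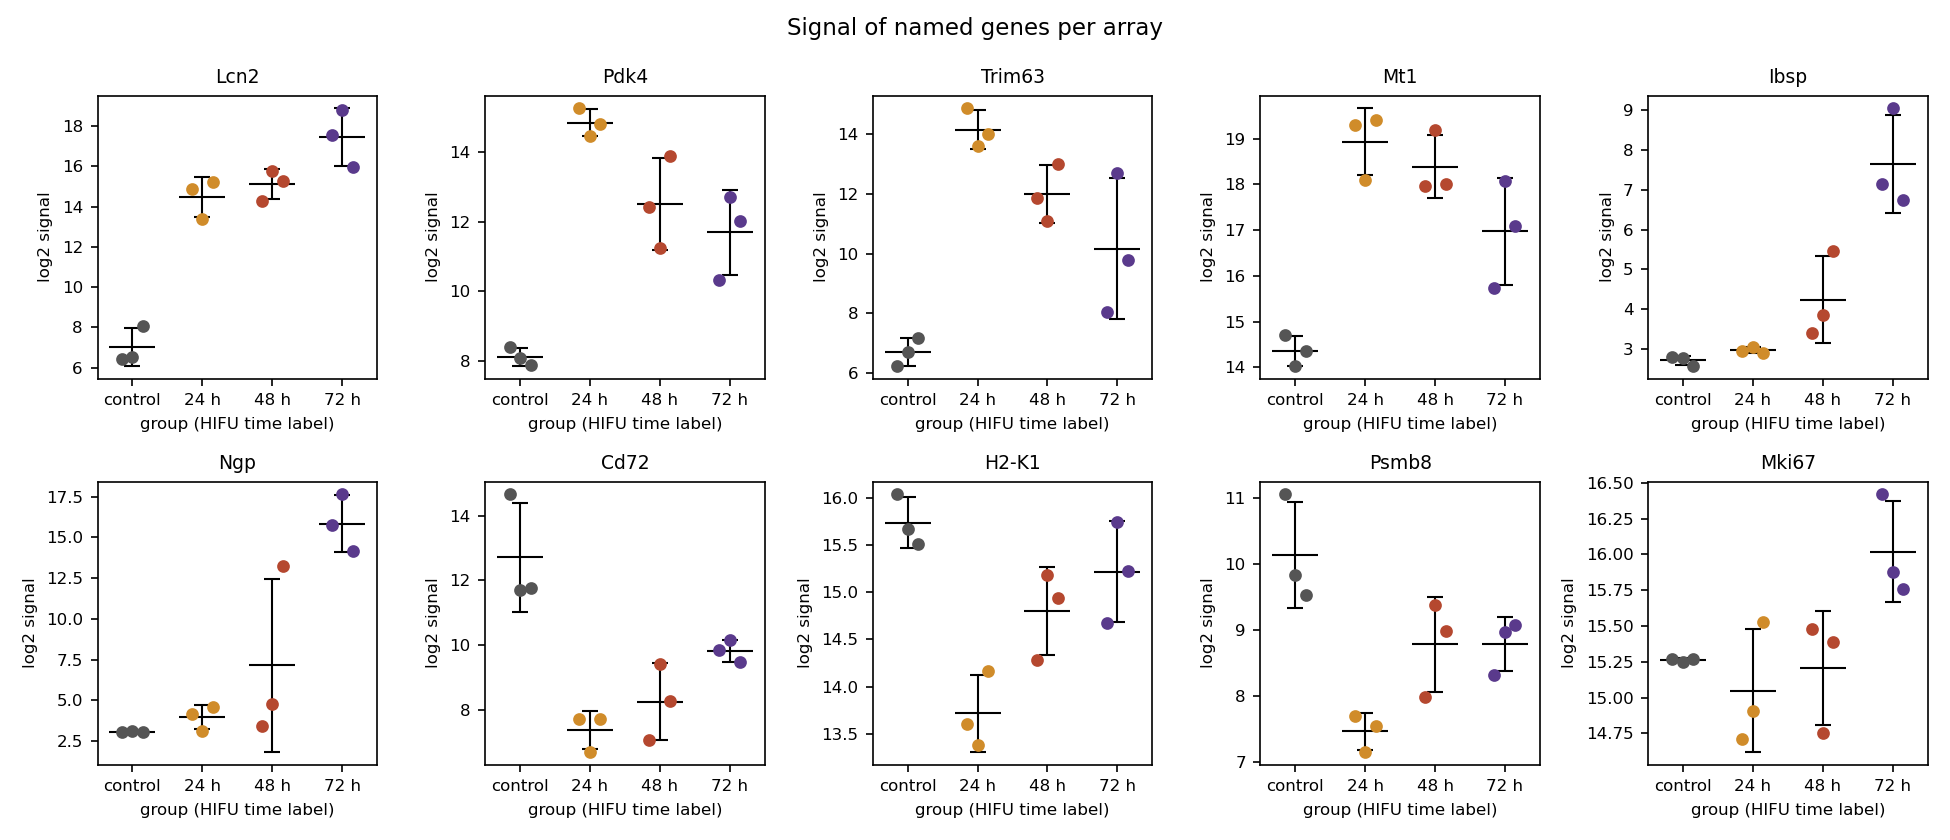
Log2 signal (y axis) of 10 named genes in each array (dots), by group (x axis); long bars are group means and whiskers the SD of 3 arrays. Lcn2 lay at 6.45 to 8.09 in controls and at 13.36 or above in all HIFU arrays, and Ngp reached 13.25 in HIFU_48h replicate 3 and 14.14 to 17.65 at 72 h.

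Myeloid and stromal lists rose alongside at 72 h: skeletal muscle (median 3.53), fibroblasts (2.46), extracellular matrix (1.99), macrophages and monocytes (1.60), phagocytosis (1.38), coagulation (1.19), complement (1.02), adipocytes (0.97), alternatively activated macrophages (0.84), chemokines (0.84), endothelial cells (0.78), mast cells (0.70), keratinocytes (0.61), inflammatory cytokines (0.53), the haem and iron response (0.50), angiogenesis (0.48), pericytes (0.48), alarmins (0.48) and p53 targets (0.23). Over all genes 0 of their members passed. Adjusted over the list alone, 17 of 18 muscle, 9 of 15 fibroblast, 7 of 18 coagulation, 4 of 15 alternatively activated macrophage and 4 of 21 haem and iron genes were higher, and between 0 and 3 in each of the others. Examples were Lyz2, lysozyme of myeloid cells (4.56 ± 1.17 SE), Chil3, a chitinase-like protein of macrophages (5.56 ± 0.90 SE), the neutrophil collagenase Mmp8 (6.72 ± 1.10 SE), the cathepsin Ctsk (3.23 ± 0.75 SE), Ppbp, a platelet chemokine (7.52 ± 1.29 SE), and Col1a1, type I collagen (4.91 ± 1.47 SE). For these 19 lists the adjusted p with an estimated correlation was between 0.473 and 0.522.

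The lists that fell at 72 h were interferon-gamma-induced genes (median -0.89, 1 of 18 lower adjusted over the list alone), ribosomal proteins (-0.89, 8 of 17), interferon-stimulated genes (-0.84, 0 of 23), MHC class I (-0.74, 2 of 15) and hypoxia (-0.65, 9 of 23), with 0 members over all genes. Ddit4 and Stc2 of the hypoxia list differed by -2.58 ± 0.45 SE and -2.38 ± 0.56 SE, and Rpl32 by -1.14 ± 0.31 SE. Their adjusted p with an estimated correlation was between 0.473 and 0.563. The cell cycle list (median -0.063) and MHC class II list (-0.19) were not called at 72 h, and Mki67, the proliferation marker Ki-67, was 0.76 ± 0.29 SE higher than control without passing (adjusted p = 0.369).

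The count at 72 h was 2 of 22206 probe sets, both higher (limma), with 2497 at an unadjusted p under 0.05, where 1110 would be expected by chance. It was 1 with a block for the replicate number, and also without control replicate 1, control replicate 2, HIFU_24h replicate 1, HIFU_24h replicate 3, HIFU_48h replicate 1, HIFU_48h replicate 2 or HIFU_72h replicate 1. It was 194 (43 higher, 151 lower) without control replicate 3, 13 without HIFU_48h replicate 3 and 5 without HIFU_72h replicate 3. It was 4 without the lowest 25% of probe sets, 1 with quantile normalization, 1846 (870 higher, 976 lower) with array weights and 1 with a muscle covariate (Ibsp 4.36 ± 0.78 SE, no longer past the threshold), under which 10 of the 26 list calls were kept, 2 ended and 13 medians reversed (the muscle list was left out of that fit). List calls ended without HIFU_72h replicate 2 for angiogenesis (0.21), complement (0.27), inflammatory cytokines (0.11), p53 targets (0.080) and pericytes (0.22). They also ended without HIFU_72h replicate 1 for interferon-stimulated (-0.31) and interferon-gamma-induced genes (-0.52), without control replicate 1 for the latter (-0.41), without control replicate 2 for p53 targets (0.22), and without control replicate 3 for alarmins (0.35) and inflammatory cytokines (0.53). Without HIFU_72h replicate 2 many medians fell by more than 1.5 times and stayed called: erythroid 2.17, matrix 1.01, macrophages 0.84, coagulation 0.71, phagocytosis 0.57, endothelial 0.40, chemokines 0.34, keratinocytes 0.31, adipocytes 0.26, mast cells 0.25, haem and iron 0.25, alternatively activated macrophages 0.18 and alarmins 0.13. The interferon-stimulated and interferon-gamma-induced medians became -1.56 and -1.36 without it, and -1.30 and -1.36 without control replicate 3. Without HIFU_72h replicate 1 the medians of MHC class I (-0.34), alternatively activated macrophages (1.36), chemokines (1.42), inflammatory cytokines (1.07), alarmins (0.82) and p53 targets (0.41) moved as much. So did interferon-stimulated (-0.56), MHC class I (-0.39), inflammatory cytokine (0.81) and p53 genes (0.36) without control replicate 1, and inflammatory cytokine (0.26) and angiogenesis genes (0.25) without control replicate 2.

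Between times, limma called 0 of 22206 probe sets in each of the 3 pairs. At an unadjusted p under 0.05 there were 863 for 48 h against 24 h, 1390 for 72 h against 48 h and 1236 for 72 h against 24 h, where 1110 would be expected by chance. From 24 h to 48 h the genes first by unadjusted p differed upward by 1.17 for Cldn34b3, 1.13 for Nampt, an enzyme of NAD synthesis, and 1.07 for Adig. Downward they differed by -1.13 for the translation factor Eif4g3, -1.06 for Whamm and -1.02 for the RNA editing enzyme Adarb1 (adjusted p = 0.999 for each). From 48 h to 72 h, Ltf differed by 5.65, Ibsp by 3.40 and Max, the partner of Myc, by 1.27, and Gdf9 by -1.23, Usp9y by -1.10 and Cldn34b3 by -0.93 (adjusted p = 0.735 for each). From 24 h to 72 h, Ltf differed by 7.40 ± 0.97 SE and Ibsp by 4.68 ± 0.59 SE (adjusted p = 0.096 for both), Acp5, the acid phosphatase of osteoclasts, by 4.06 (adjusted p = 0.265), Retreg1 by -3.30 and Cnksr1 by -3.27 (adjusted p = 0.341 for both) and Pdk4 by -3.16 (adjusted p = 0.455). The signals of Cldn34b3 at 24 h and 72 h, of Usp9y at 72 h, and of Ltf (3.14) and Ibsp (2.97) at 24 h were among the lowest 25%, so the sizes of their differences are uncertain.

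Of the 45 lists, camera called 7 between 24 h and 48 h, 16 between 48 h and 72 h and 22 between 24 h and 72 h, and 0 in each with an estimated correlation (lowest adjusted p = 0.662). From 24 h to 72 h the neutrophil list rose by a median of 4.05 (12 of 19 members adjusted over the list alone) and the interferon-gamma-induced list by 2.24 (13 of 18), which left it -0.89 from control. MHC class I genes rose by 1.27 (6 of 15) and cell cycle genes by 0.75 (0 of 22), with adjusted p = 0.662 with an estimated correlation for each of the 4 lists. The count of genes from 48 h to 72 h was 2 without HIFU_48h replicate 3; that from 24 h to 72 h was 7 without HIFU_48h replicate 3, 3 without HIFU_72h replicate 2, 1 without HIFU_72h replicate 3, 7 with array weights and 2 with only the 2 groups compared.

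Averaged over the 3 times, 4 probe sets rose against control and 0 fell (limma). They were Lcn2 by 8.65 ± 0.61 SE (adjusted p = 0.000287), Pdk4 by 4.91 ± 0.54 SE (adjusted p = 0.0163), Retreg1 by 3.94 ± 0.49 SE and Mt1 by 3.73 ± 0.46 SE (adjusted p = 0.0273 for both). The F test for a difference at any time called 2, Lcn2 (adjusted p = 0.00218) and Pdk4 (adjusted p = 0.049). The count for the mean was 398 (94 higher, 304 lower) and that for the F test 148 without control replicate 3, and 3787 (1596 higher, 2191 lower) and 1488 with array weights. The counts were 15 (12 higher, 3 lower) and 4 without the lowest 25% of probe sets, 14 (12 higher, 2 lower) and 5 with an intensity trend and robust estimation, and 14 (11 higher, 3 lower) for the mean with median centring. Both were 1 with a block for the replicate number, without control replicate 1, control replicate 2, HIFU_24h replicate 1, HIFU_24h replicate 3 or HIFU_72h replicate 3, and with a muscle covariate. The count for the mean was 44 without HIFU_24h replicate 2, 9 without HIFU_72h replicate 1 and 18 without HIFU_72h replicate 2, and that for the F test 1 without HIFU_48h replicate 1, 10 without HIFU_48h replicate 3, 5 without HIFU_72h replicate 1 and 12 without HIFU_72h replicate 2.

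The changes at the 3 times resembled one another across probe sets, which are not independent replicates. The log2 differences of 24 h and 48 h correlated with r = 0.85, those of 24 h and 72 h with 0.721 and those of 48 h and 72 h with 0.789. All were taken against the same 3 controls, which alone gave 0.499, 0.5 and 0.5 in simulated groups without an effect. The covariances were 0.412, 0.374 and 0.426 against 0.104 in the simulation. Lcn2 was the 1 probe set past the threshold at each pair of times, where independent lists of that size would share 0.000495, 0.000991 and 9.01e-05. The 3 controls were too few to be split, so part of the excess may come from the shared controls. The 3 HIFU groups also shared a rise of muscle genes (list medians 3.37, 3.31 and 3.53), which may add to the resemblance. Correlations with the muscle covariate are not given here, so its part was not tested.

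Genes chosen in advance for tumor immunity, stress and tumor identity gave 0 calls at any time. The checkpoint ligand Cd274 differed by -1.93 ± 0.87 SE at 24 h, -0.64 at 48 h and -0.43 at 72 h (lowest adjusted p = 0.506), and the checkpoint receptors Pdcd1 and Ctla4 by -0.39 and 0.57 at 24 h. The T-cell coreceptors Cd8a and Cd4 differed by -1.10 ± 0.39 SE and 0.16 ± 0.30 SE at 24 h, Ifng by -0.40 and the granzyme Gzmb by -1.06. Pdcd1, Cd8a, Gzmb and Tnf (-0.96) had mean signals among the lowest 25% at 24 h, where small changes are hard to see. Haem oxygenase, Hmox1, differed by 3.34 ± 1.21 SE, 3.05 and 3.19 at 24, 48 and 72 h and arginase, Arg1, by 3.66 ± 1.51 SE, 3.55 and 3.54. The heat shock gene Hspa1a differed by 0.76 ± 0.40 SE at 24 h, 0.36 at 48 h and -0.19 at 72 h. The cytokine Il6 differed by 0.47, -1.68 and -1.24 and Il1b by 0.84, 1.11 and 1.71. Vegfa, the angiogenic growth factor, differed by -0.73, -1.21 and -1.24. The oncogene Mycn differed by -0.07, 0.21 and -0.46 and Th, tyrosine hydroxylase of catecholamine synthesis, by 0.23, 0.42 and -0.08 (adjusted p = 0.862 or more for both at each time).

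The neuroblastoma and sympathoadrenal identity list was not called at any time, with medians of 0.31, 0.42 and 0.16 over 27 members at 24, 48 and 72 h. Also not called at any time were T cells (median at 24 h -0.13), regulatory T cells (0.13), dendritic cells (-0.11), checkpoints and co-stimulation (-0.097), classically activated macrophages (0.090), the unfolded protein response (-0.063), glycolysis (-0.28), oxidative phosphorylation (-0.057), the TGF-beta pathway (0.17) and Schwann cells (0.095). In 15 of 135 list results, 0 of them called, the median, the mean and the test differed in sign, among them the neuroblastoma list at 72 h (mean -0.12) and the heat shock list at 72 h (median -0.18, mean 0.21).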

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

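The tests of the interferon pattern and the comparison of the 72 h arrays with earlier arrays were chosen after the result was seen.

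Several lists differed between times by camera with the preset correlation, and none with an estimated correlation. Interferon-gamma-induced genes were higher at 48 h than at 24 h by a median of 1.4, MHC class I genes by 0.637 and keratinocyte genes by 0.613, and immediate-early genes were lower (-0.477), each with adjusted p = 0.662 with an estimated correlation. The interferon-gamma median of HIFU_48h replicate 1 (-3.307) lay within the range of the 24 h arrays (-3.768 to -2.547). Against control, the keratinocyte median at 48 h was 0.702, and 0.257 without HIFU_48h replicate 3. From 48 h to 72 h neutrophil genes were higher by 2.977 (adjusted p = 0.662 with an estimated correlation), erythroid genes by 2.325 (0.693), cell cycle genes by 0.627 (0.841) and interferon-stimulated genes by 0.927 (0.883). The last rested largely on HIFU_72h replicate 2. Without that array the interferon-stimulated median at 72 h was -1.56 against control, near the -1.85 at 48 h. From 24 h to 72 h neutrophil genes were higher by 4.047, interferon-gamma-induced genes by 2.24, MHC class I genes by 1.267 and cell cycle genes by 0.748 (adjusted p = 0.662 with an estimated correlation for each).

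For some single genes the 3 arrays of one time lay above the control mean and those of the other below it, and the difference between the times was not tested for this selection. These were Nampt (1.13 from 24 h to 48 h and -0.8 from 48 h to 72 h), Adarb1 (-1.02) and Whamm (-1.06) from 24 h to 48 h, Hspa1a (-0.55), Max (1.27) and Gdf9 (-1.23) from 48 h to 72 h, and Max (1.13) and Acp5 (4.06) from 24 h to 72 h. In limma 0 genes passed for any pair of times.

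Marrow genes, and some bone genes, were high at 72 h. Of 56 measured members of 4 lists not used in the report (erythroid, granulocyte precursor, bone matrix and osteoclast genes), 28 lay above all controls in all 72 h arrays, where 2.8 would be expected by chance: 16 of 22 erythroid, 4 of 9 granulocyte precursor, 4 of 14 bone and 4 of 11 osteoclast genes. Of the 56, 32 had control signals above the lowest 25%, so the differences of the others are uncertain in size. Members of a list move together and share the 3 controls, so the excess over 2.8 is not a test. Bone and marrow tissue in the sampled pieces may be a source. For bone this is weak, since the bone median in HIFU_72h replicate 3 (0.048) lay below control replicate 1 (0.062). Mature neutrophils alone were argued against by the 47 erythroid, bone and osteoclast members, whose median change was 0.533. That median was carried by the erythroid genes (1.405), against 0.192 for bone and 0.253 for osteoclast genes. The erythroid list of the report had already risen at 72 h (median 3.41), so a rise of further erythroid genes could be foreseen. The argument therefore rests mainly on erythroid genes and adds little to that list. A response to HIFU at 72 h cannot be told apart from bone and marrow tissue in the pieces, since the sampled region is not known for any array. The genes were not limited to the 72 h arrays. HIFU_48h replicate 3, 1 array of an earlier time, lay within their range (0.45 against 0.29 to 0.793). A single array does not decide between the explanations.

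Interferon-gamma and MHC class I genes were low at 24 h. Dilution of tumor tissue by muscle and stroma was argued against as the whole cause. The 37 neuroblastoma and neuronal genes had a median of 0.313 (quartiles over genes -0.24 to 0.85), while MHC class I genes had -1.813. Per array, the former ran from -0.243 to 0.897 at 24 h and from -0.893 to 1.103 in controls. The interferon-gamma medians of control replicates 1, 2 and 3 ran the other way (0.993, -0.212 and -0.725). A part played by tissue make-up therefore stays open. Control replicate 1 alone was argued against, since the interferon-gamma median without it was -2.522. Fewer lymphocytes that make interferon-gamma cannot be told apart from a change in their signaling: the 33 T cell and cytotoxic genes had a median of -0.237, with 11 of them among the lowest 25% of signals in controls. Taken apart, the cytotoxic lymphocyte list was called lower by camera with the preset correlation (-0.443), and the T cell list was not called. The cytotoxic call ended without HIFU_24h replicate 2 (-0.432). The effect of HIFU itself, which the design names, stays open as a biological explanation.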

How the results depend on the processing

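The muscle covariate and the fit without the 4 arrays high in marrow genes were chosen after seeing the data. The cause was not tested for the changes below, except where the alternative's construction shows it.

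Lcn2 at 72 h passed in all 21 alternatives (log2 difference 8.80 to 11.16, adjusted p from 3.08e-06 to 0.0413). Lcn2 at 24 h passed in 17 of 22 and at 48 h in 16 of 22, Pdk4 and Retreg1 at 24 h in 17, Trim63, Fbxo32 and Mt1 in 14, Myf6, Mt2, Cnksr1 and Abra in 11, Hspb7 in 9, Cd72 in 8, and Ibsp at 72 h in 9 of 21.

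Counts of genes at 24, 48 and 72 h, for the mean of the times and for the F test were 12, 1, 2, 4 and 2. With a block for the replicate number they were 3, 0, 1, 1 and 1. Without the lowest 25% of probe sets they were 4 at 72 h, 15 for the mean and 4 for the F test. Quantile normalization gave 1 at 72 h, median centring 14 for the mean, and an intensity trend with robust estimation 14 for the mean and 5 for the F test. Array weights gave 1118, 944, 1846, 3787 and 1488 (more lower than higher in each of the first 4), and 7 from 24 h to 72 h. The weights, estimated from the same 12 arrays, ran from 0.306 for HIFU_72h replicate 2 to 4.19 for control replicate 2. Control replicates 1 and 3 had 1.25 and 0.715, so the weighted comparisons with control lean on control replicate 2. Only the groups compared gave 6 at 48 h and 2 from 24 h to 72 h, and no value for the mean or the F test. An unadjusted p under 0.05 with a 2-fold change gave 1197 (498 higher, 699 lower), 1623 (610 and 1013), 1620 (1002 and 618), 1500 (785 and 715) and 1417, and 154, 395 and 535 for 48 h against 24 h, 72 h against 48 h and 72 h against 24 h, since it makes no correction. Without the 4 arrays high in marrow genes the count at 48 h was 2, and the calls of keratinocyte, erythroid and hypoxia genes at 48 h ended. The pseudocount was not run, because the values were already on a log scale.

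Lists called at the 3 times were 25, 24 and 26, and 0, 0 and 0 with an estimated correlation and 1, 0 and 1 with fry. With the muscle covariate the gene counts were 0, 0, 1, 1 and 1. The differences became smaller while remaining several times their errors, for example Pdk4 from 6.74 ± 0.66 SE to 6.23 ± 0.89 SE, Mt1 from 4.56 ± 0.57 SE to 3.52 ± 0.63 SE and Hspb7 from 5.91 ± 0.83 SE to 3.90 ± 0.72 SE at 24 h, and Lcn2 from 8.09 ± 0.74 SE to 6.48 ± 0.75 SE at 48 h; the fit also has fewer residual degrees of freedom. With it, 17, 16 and 16 lists were called. The balance turned, from 15 higher and 10 lower to 2 and 15 at 24 h, from 15 and 9 to 3 and 13 at 48 h, and from 21 and 5 to 7 and 9 at 72 h. Of the earlier calls 8, 8 and 10 were kept, and 8, 7 and 6 lists were called only with the covariate. The muscle score, which takes differences from the mean of all 12 arrays, lay at -0.657 or lower in controls and -0.628 or higher in HIFU arrays. That gap is narrow, and the medians against the control mean overlap (2.18 in control replicate 3, 2.02 in HIFU_24h replicate 2). The score still follows the groups closely, so this covariate also removes part of any treatment difference. With the muscle covariate, interferon-gamma-induced genes (-3.472), interferon-stimulated genes (-2.326), MHC class I antigen presentation (-2.07) and hypoxia (-0.919) kept their calls at 24 h against control. So did neutrophils (4.24) and erythroid cells and blood (2.212) at 72 h against control. The kept interferon, MHC and hypoxia medians were larger in size than without the covariate. Other kept calls had much smaller medians. Among these were cell cycle at 24 h (-0.258 from -0.72), and neutrophils (0.664 from 2.317) and histones (-0.196 from -0.543) at 48 h. At 72 h they included alarmins (0.115 from 0.48), coagulation (0.56 from 1.187) and ribosomal proteins (-0.224 from -0.89). Calls ended without reversal for B cells (0.191), alternatively activated macrophages (0.083), adipocytes (0.037), DNA replication (-0.249), histones (-0.244), immediate-early genes (0.050) and coagulation (0.174) at 24 h. At 48 h they ended for alternatively activated macrophages (0.124), adipocytes (0.162), cell cycle (-0.043), coagulation (0.039), erythroid cells (0.150), haem and iron (0.053) and ribosomal proteins (-0.112), and at 72 h for fibroblasts (0.184) and mast cells (0.195). Fibroblasts at 24 h and phagocytosis at 48 h passed in the other direction (camera adjusted p = 0.0127 and 0.00674). There were 30 reversed list medians, all under this covariate, of 1544 comparisons, and 0 of 2417 for genes. At 24 h they were neutrophils -0.118, mast cells -0.326, endothelial cells -0.205, fibroblasts -0.635, pericytes -0.416, chemokines -0.3, matrix -0.302, haem and iron -0.147 and ribosomal proteins 0.076. At 48 h they were mast cells -0.254, endothelial cells -0.229, fibroblasts -0.239, pericytes -0.284, chemokines 0.004 (with the test turned), DNA replication 0.046, matrix -0.098 and phagocytosis -0.764. At 72 h they were macrophages -0.151, alternatively activated macrophages -0.271, endothelial cells -0.278, pericytes -0.396, adipocytes -0.043, chemokines -0.179, inflammatory cytokines -0.007, complement -0.249, p53 targets -0.175, matrix -0.018, angiogenesis -0.004, haem and iron -0.04 and phagocytosis -0.032.

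Leaving out 1 array at a time gave 0 to 253 (52 higher, 201 lower) genes at 24 h, 0 to 312 at 48 h, 1 to 194 at 72 h, 0 to 0, 0 to 2 and 0 to 7 between times (48 h against 24 h, 72 h against 48 h, 72 h against 24 h), 1 to 398 for the mean and 1 to 148 for the F test. Called lists ran from 18 to 26, 20 to 24 and 24 to 28, and the correlations of changes from 0.759 to 0.896, 0.594 to 0.798 and 0.661 to 0.848.

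For single genes and lists under the other alternatives, 993 gene results kept direction and side of the threshold, 43 newly passed and 37 no longer passed; for lists 435 kept both, 179 no longer passed and 30 reversed. Median centring moved the median of all genes by -0.142 at 72 h. Among probe sets with an unadjusted p under 0.05 and a 2-fold change, it lowered the share higher at 72 h from 61.9% to 47.2%. Residuals of arrays with the same replicate number correlated by more than 0.1 in 4 of 18 pairs (median -0.133), so arrays were not treated as pairs. Signals among the lowest 25%, under 3.55, limit what can be seen of dim genes.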

Other observations

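The tests of atrophy genes against the muscle list, and the muscle covariate for the glucocorticoid genes, were chosen after the result was seen.

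Dlk1, a neuroendocrine surface protein of the neuroblastoma list, differed by -5.82 ± 1.31 SE at 24 h, -6.57 at 48 h and -5.29 at 72 h (limma adjusted p = 0.213, 0.199 and 0.266). Its control signals were 16.45, 15.65 and 10.12.

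A set of 9 genes, labelled muscle atrophy genes here, was high after HIFU. The label does not mean that atrophy itself was measured. The 9 genes, Trim63, Fbxo32, Pdk4, Retreg1, Klhl38, Abra, Cnksr1, Mustn1 and Hspb7, were put together after the 24 h calls were seen and hold 7 of them, so their medians of 5.64, 4.38 and 2.99 at 24, 48 and 72 h partly restate those calls. A larger share of muscle in the HIFU samples cannot be told apart from a change within muscle. Relative to the muscle list, the 9 HIFU arrays lay 0.717 above the 3 controls (-1.994 ± 1.395 SD against -2.711 ± 1.603 SD, exact permutation p = 0.486 over 220 splits). The subtraction assumes that these genes rise 1 for 1 with muscle. In controls they did not: atrophy means were 7.482, 7.266 and 7.766 at muscle means of 8.791, 9.631 and 12.224. This p-value therefore cannot decide. Atrophy means in HIFU arrays ran from 9.162 to 13.791, but most of these genes were picked by their 24 h calls. Control replicate 3, HIFU_24h replicate 2 and HIFU_72h replicate 1 had nearly equal muscle means (12.224, 12.224 and 12.223) and atrophy means of 7.766, 12.042 and 9.162, 1 array each. From 24 h to 72 h the atrophy genes differed by -2.736 relative to the muscle list, but genes picked by their 24 h calls favour a fall, so this decides nothing.

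A glucocorticoid or stress hormone response cannot be told apart from muscle content either. The median of 17 glucocorticoid-induced genes was 0.998 ± 0.481 SD in HIFU arrays and 0.012 ± 0.207 SD in controls (exact permutation p = 0.00909, smallest possible 0.00455), and it moved with the muscle mean over the 12 arrays (r = 0.884). With the muscle mean as a covariate the difference was 0.206 ± 0.310 SE. At the nearly equal muscle means it was 0.25 in control replicate 3, 0.39 in HIFU_24h replicate 2 and 0.427 in HIFU_72h replicate 1.

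Splits of the arrays were counted, the true grouping included in each count. With 6 arrays there are 10 splits, too few for a share under 0.05. At 24 h, 1 split gave as many genes (12, highest other 0) and 2 as many lists (25, highest other 26); at 48 h, 1 gave as many genes (1, highest other 0) and 1 as many lists (24, highest other 22); at 72 h, 2 gave as many genes (2, highest other 18) and 4 as many lists (26, highest other 33). Between times all 10 splits gave as many genes in each of the 3 pairs (0, highest other 0). For the mean of the times, 5 of 100 splits gave as many genes (4, highest other 2621), and for the F test 6 of 100 (2, highest other 19), so chance cannot be excluded for either. The split with 2621 set HIFU_24h replicate 1, HIFU_48h replicate 2 and HIFU_72h replicate 2 against the rest, the highest in muscle genes of their groups, which points to a structure of the samples.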
